A study of Mus musculus with 6 samples.

How the data were processed

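Gene expression in isolated pancreatic islets of 6-week-old mice was measured by RNA sequencing in 6 libraries, 3 from Paupar wild-type (WT) and 3 from Paupar knockout (KO) mice, grouped by the genotype and replicate number in the labels. Per the labels' protocols, islets were freed with collagenase, total RNA of high integrity was extracted with a spin-column kit for small samples, and libraries were made with a TruSeq RNA kit and read on a HiSeq2000. The submitters' processing notes name CASAVA 1.8.2, HISAT2 2.1.0, HTSeq, DESeq2 and the mouse genome build mm9. The gene annotation, the counting options and whether strand was used are not given in the sources used here. Without strand, reads of a gene and of its antisense partner cannot be told apart, and reads shared by near-identical copies may be lost or split.

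The deposited table holds raw read counts, whole numbers that the authors had not normalized, for 53670 genes in each of the 6 libraries. Each library's column was matched to its sample by name, and 0 columns were left over. A set of 24 gene names had been turned into dates, as spreadsheet programs do, and these genes are not named here. Total counts per library ran from 25733194 to 27285009. A floor of 3 counts, the most that a count of 0 allows, was worth 0.110 to 0.117 CPM (read counts scaled to the library's total), and such floors and the counting interval given for Paupar cover counting error only.

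Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with genotype as the group, which left 15915. Libraries were scaled by TMM factors, and genotype was tested with the quasi-likelihood F-test. P-values were adjusted by the Benjamini-Hochberg method and called at an adjusted p below 0.05. Fold changes are log2 of KO over WT with standard errors (SE), and levels are CPM scaled by TMM, as mean ± SD over 3 libraries. Shares of counts were compared by two-sided exact permutation tests, for which 3 against 3 libraries cannot give a p below 0.1. Intervals of medians are 95% bootstrap intervals from 10000 draws over genes, which are not independent replicates.

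The main test, the alternatives, 31 gene lists (islet cell types, other cell types that islet preparations can hold, PAX6 targets, locus neighbours and pathways) and the rule for naming genes were fixed before the data were examined. By that rule the text names Paupar, Pax6, Pax6os1 and neighbours. It names up to 12 genes with the largest increase and up to 12 with the largest decrease among called genes whose groups did not overlap and whose mean CPM was at least 1, leaving out predicted and sex-linked genes. In each list it names the main hormones, up to 4 called members and otherwise the first tested members as written. Other genes named, among them the list members that passed when adjusted over the list alone, were chosen after their values were seen. Some genes that the rule or a list would name are not reported here. Lists with at least 4 tested members, the sex-linked one excepted, were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over 28 lists. Camera with an estimated correlation was run beside it. Of these 28 lists none was called with the estimated correlation.

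Exonic length and GC content came from GENCODE vM1 on mm9, matched by symbol or by a unique synonym for 14779 of the 15915 tested genes (92.9%). Paupar is not in that annotation, so no mm9 coordinates are given for it.

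The alternatives were DESeq2 size factors within edgeR, library sizes without the 10 most abundant genes, no low-count filter, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust empirical Bayes, the replicate number as a block, the acinar list as a covariate, an adjusted p below 0.1, and leaving out each library. Chosen after seeing the data were a sex covariate, the 3 WT libraries against KO replicate 1 alone, smooth offsets per library on exonic length and GC content, and 3 further gene lists. On simulated counts for KO against WT (15915 genes), edgeR recovered 21.0% of genes changed 1.5-fold, 55.7% of those changed 2-fold and 86.8% of those changed 4-fold, and 9.76% of its calls had not been changed. On the same counts 24.9% of the DESeq2 calls and 10.9% of the limma-voom calls had not been changed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.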

Results

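RNA was sequenced from isolated pancreatic islets, the clusters of hormone-secreting cells of the pancreas, of 6-week-old mice with and without Paupar, a long noncoding RNA gene beside Pax6. There were 3 WT and 3 KO libraries, with 26969781, 25882101 and 25733194 gene counts in WT replicates 1 to 3 and 27285009, 26915566 and 26967317 in KO replicates 1 to 3. The single comparison of the design, KO against WT, asks which islet transcripts differ when Paupar is missing. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical, except that the sex-linked transcripts given below show KO replicate 1 not to come from the same animals as KO replicates 2 and 3. Libraries of one group differed by more than counting noise, with a chi-square per degree of freedom of 26.7 to 89.3. Pairs of a WT and a KO library overlapped that range, at 27.8 to 132.

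Paupar itself was almost lost from the KO libraries. WT replicates 1 to 3 held 177, 252 and 111 Paupar counts (6.56, 9.74 and 4.31 CPM of the total count), and KO replicates 1 to 3 held 4, 0 and 4 (0.147, 0 and 0.148). Pooled over libraries the level was 69.7-fold lower in KO, with a 95% counting interval of 35.1 to 162, which leaves 1.43% of the WT level. In edgeR's fit the log2 fold change was -5.98 (SE 0.66, adjusted p = 0.0446). DESeq2 gave no adjusted p for this gene. In NCBI's gene table for a later mouse assembly Paupar lies within the interval of Pax6os1, and Pax6 is the next gene by start.

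Pax6, which encodes a paired-box transcription factor of endocrine and neural cells, showed no difference that passed the test. Its level was 246 ± 8.85 CPM in WT and 250.3 ± 31.8 in KO (chromosome 2, 105509053 to 105543317 in mm9), a log2 fold change of 0.03 (SE 0.10, adjusted p = 0.924). Pax6os1, a noncoding gene that overlaps the start of Pax6 (chromosome 2, 105376237 to 105510487), stood at 8.08 ± 1.83 CPM in WT and 12.6 ± 3.07 in KO, and its log2 fold change of 0.64 (SE 0.23) did not pass (adjusted p = 0.256). Of 12 tested neighbours of the locus, none passed in edgeR over all genes or adjusted over the list alone, and their median log2 fold change was 0.11 (camera adjusted p = 0.204). Among them were Elp4, a subunit of the Elongator complex, at 0.21 (SE 0.13, adjusted p = 0.476), and Immp1l, a mitochondrial inner membrane peptidase, at 0.31 (SE 0.08, adjusted p = 0.171).

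**Figure D1:**
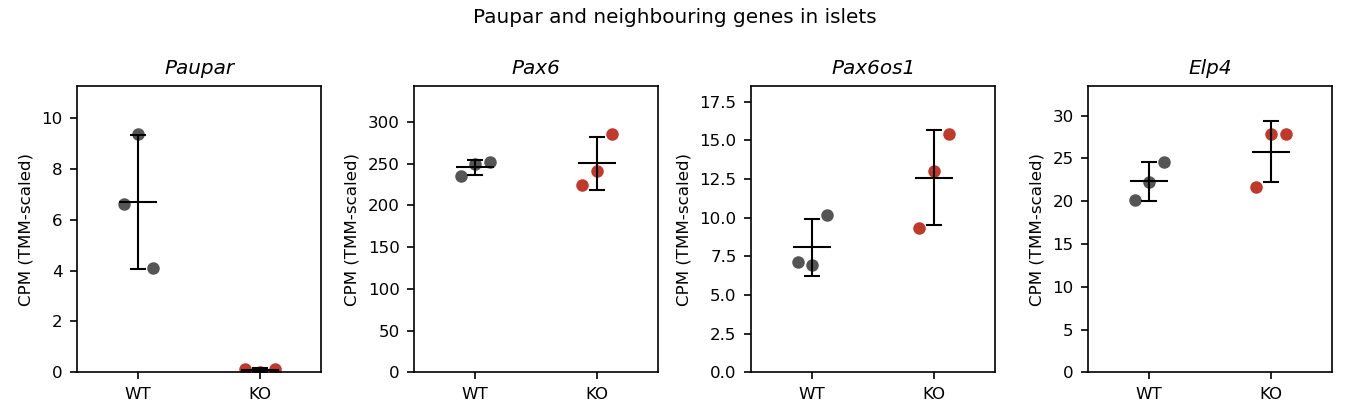
Paupar, Pax6, Pax6os1 and Elp4 in the 3 WT and 3 KO libraries, in TMM-scaled CPM on the vertical axis. Points are libraries, the long bar is the mean and the whiskers are the SD. Paupar is near 0 in every KO library, while the Pax6 means are 246 and 250.3.

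Apart from Paupar, the transcripts that fell in KO islets included the nuclear long noncoding RNAs Malat1, Neat1 and Meg3 and several large messenger RNAs for chromatin and RNA-processing proteins. Malat1, a noncoding RNA of nuclear speckles (chromosome 19, 5795690 to 5802671), fell from 73.2 ± 24.0 to 15.3 ± 2.40 CPM, a log2 fold change of -2.26 (SE 0.24, adjusted p = 0.0446). Meg3, an imprinted, maternally expressed noncoding RNA (chromosome 12, 110779211 to 110809936), fell from 37.7 ± 7.74 to 8.14 ± 1.07 CPM (-2.21, SE 0.17, adjusted p = 0.0364). Neat1, the scaffold of paraspeckles (chromosome 19, 5824708 to 5845478), fell from 17.6 ± 1.24 to 8.22 ± 0.703 CPM (-1.10, SE 0.11, adjusted p = 0.0446). Crebbp, a histone acetyltransferase and transcriptional coactivator (chromosome 16, 4084048 to 4213404), fell from 51.0 ± 3.05 to 25.7 ± 1.16 CPM (-0.99, SE 0.08, adjusted p = 0.0364). Kmt2a, a histone methyltransferase (chromosome 9, 44611438 to 44689379), fell from 119.7 ± 17.4 to 56.9 ± 3.34 CPM (-1.07, SE 0.11, adjusted p = 0.0446).

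In all, edgeR called 27 genes lower and 0 higher in KO at an adjusted p below 0.05, with 1493 lower and 1113 higher at an unadjusted p below 0.05. All 27 were lower in each KO library than in each WT library. Over all tested genes 23.4% had groups that did not overlap, where chance gives 10%. The histone methyltransferases Dot1l (-0.99) and Kmt2b (-0.63) and the histone demethylase Kdm6b (-0.77) were among the 27. So were the RNA-binding or splicing-related genes Sfswap (-0.82), Rbm5 (-0.65), Acin1 (-0.59) and Sugp2 (-1.01), and Tnrc6b (-0.80), which encodes a protein of microRNA silencing. Celsr3, an atypical cadherin, fell by 0.88 on the log2 scale, the microtubule-associated Eml5 by 0.93, Fam193b by 1.34 and Prrc2c by 0.95. DESeq2 called 437 genes lower and 209 higher, among them 25 of the 27, the other 2 having no adjusted p. The count rested on single libraries and on the test: it was 0 in limma-voom, with the acinar or the sex covariate, with the length and GC offsets, and without WT replicate 1, WT replicate 2, KO replicate 2 or KO replicate 3, while without WT replicate 3 it was 80 lower and 9 higher. Without KO replicate 1, the only calls were 4 Y-linked genes lower and Xist higher.

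**Figure D2:**
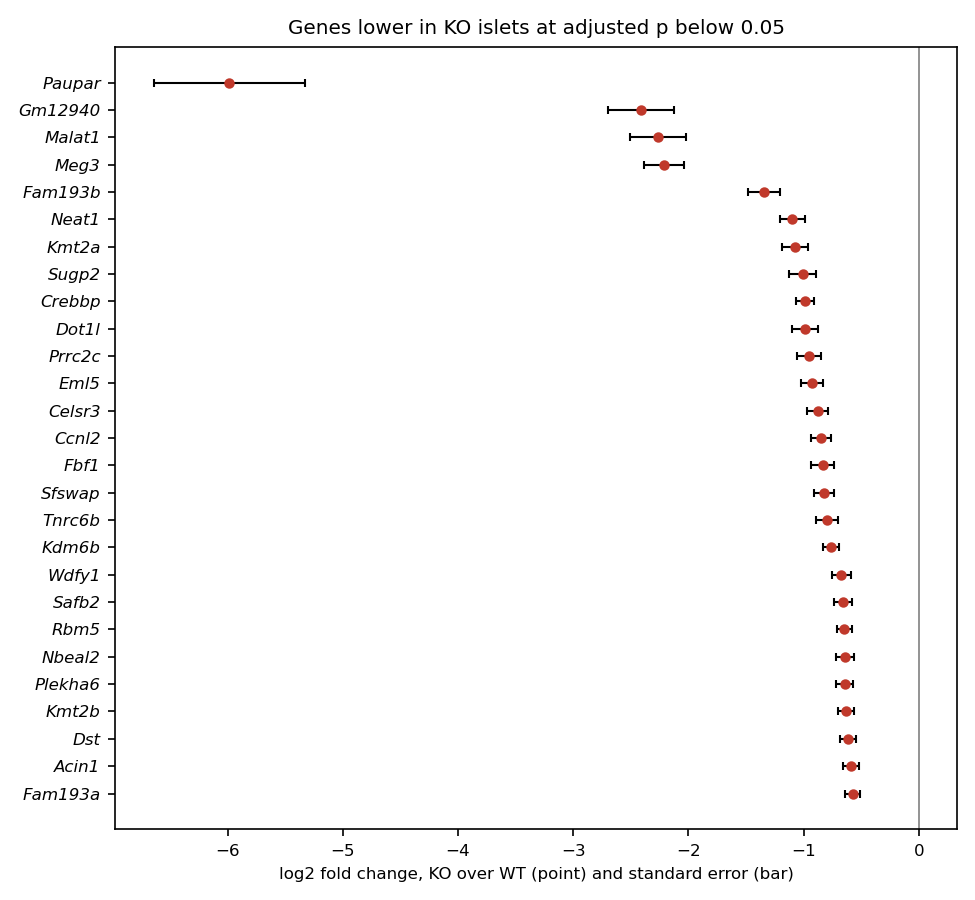
Log2 fold change, KO over WT, of the 27 genes at an adjusted p below 0.05 in edgeR (points, horizontal axis) with their standard errors (bars). All 27 lie below 0, from Paupar at -5.98 to Fam193a at -0.57.

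Sex-linked transcripts and gene length moved along with these groups. Xist, the noncoding RNA of X inactivation, had 1, 6 and 3 counts in the WT libraries and 0, 1120 and 862 in KO replicates 1 to 3. Ddx3y, a Y-linked helicase gene, had 1715, 1316 and 1830 counts in WT and 1693, 2 and 0 in KO, so KO replicate 1 resembled the WT libraries in both genes and KO replicates 2 and 3 did not. With sex as a covariate, the effect of genotype therefore rests on KO replicate 1 alone against the WT libraries. Across 10897 genes the fold change had a Spearman correlation of -0.30 with exonic length and -0.22 with exonic GC content (genes are not independent replicates). For each library's deviation from the gene's mean, the correlation with length was 0.22, 0.16 and 0.19 in WT replicates 1 to 3. It was -0.31, -0.24 and -0.064 in KO replicates 1 to 3. With GC content the values were 0.035, 0.33 and -0.018 in WT and -0.11, -0.089 and -0.22 in KO. The fifth of genes with the shortest exonic length had a median log2 fold change of 0.10 and the fifth with the longest one of -0.092. The 26 called genes with annotation, all but Paupar, had a median exonic length of 8459 bp, against 3524 bp for all tested genes with annotation.

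**Figure D3:**
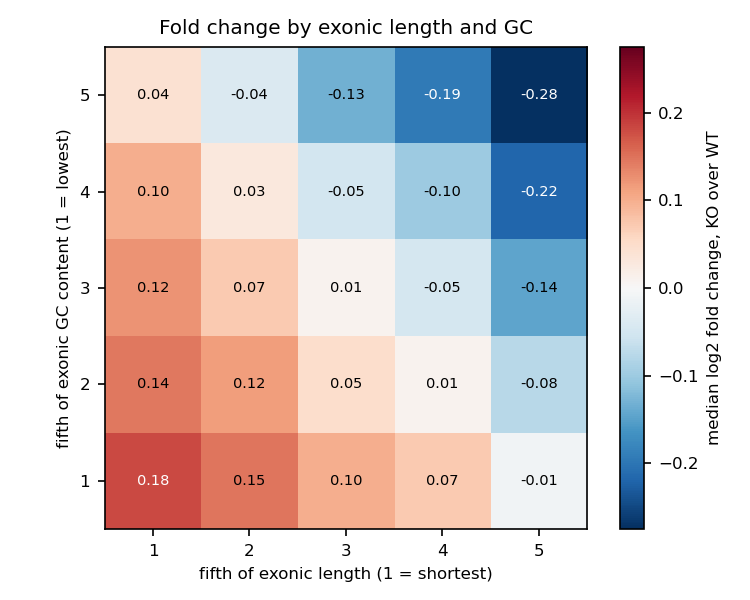
Median log2 fold change, KO over WT, in bins of equal gene number by exonic length (horizontal axis, 1 the shortest to 5 the longest) and by exonic GC content (vertical axis, 1 the lowest to 5 the highest). The median runs from 0.18 in short genes of low GC content to -0.28 in long genes of high GC content.

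Among the islet's endocrine cells, alpha cell genes were lower and beta cell genes higher in KO as lists with the preset correlation but not with an estimated one (adjusted p = 0.556 for both), and the hormone genes did not pass. Gcg, which encodes glucagon, was at 37594 ± 5554 CPM in WT and 32932 ± 2452 in KO (log2 fold change -0.19, SE 0.21, adjusted p = 0.687). The insulin genes Ins1 (0.36, SE 0.21, adjusted p = 0.447) and Ins2 (0.28, SE 0.26, adjusted p = 0.634), near-identical copies whose reads may be split, were higher in every KO library than in every WT library. Together they took 20.8 ± 1.70% of counts in WT and 24.4 ± 0.119% in KO (exact permutation p = 0.1, the smallest possible). Gcg took 3.85 ± 0.445% of counts in WT and 3.21 ± 0.257% in KO (exact permutation p = 0.1). The somatostatin gene Sst was at -0.02 (SE 0.27), the pancreatic polypeptide gene Ppy at -0.33 (SE 0.31) and the ghrelin gene Ghrl at -0.81 (SE 0.27, adjusted p = 0.228).

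The alpha cell list had a median log2 fold change of -0.17 over 20 tested members (camera adjusted p = 0.00352, and adjusted p = 0.556 with an estimated correlation). Over all genes no member passed in edgeR, and adjusted over the list alone 4 fell, 0 rose and 16 did neither. Among those that fell were the Iroquois homeobox genes Irx1, from 17.4 ± 1.94 to 10.8 ± 1.89 CPM (-0.68, SE 0.15, adjusted p = 0.141 over all genes), and Irx2, from 20.9 ± 1.71 to 13.4 ± 1.44 CPM (-0.64, SE 0.11, adjusted p = 0.0974 over all genes). The 14 members outside a set of 6 transcription factor genes had a median of -0.12. Among these 14 were the somatostatin receptor gene Sstr2 at -0.85 (SE 0.34) and the amino acid transporter gene Slc38a5 at -0.26 (SE 0.20). The carrier protein gene Ttr was at 0.02 (SE 0.15). The zinc finger gene Peg3, which may itself count as a transcription factor gene, was also placed there, at -0.07 (SE 0.17). Without KO replicate 1 the list had an adjusted p of 0.0518, and without WT replicate 1 its median was -0.051 (adjusted p = 0.0154).

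The beta cell list had a median of 0.26 over 20 members (camera adjusted p = 0.00566, and adjusted p = 0.556 with an estimated correlation), and adjusted over the list alone none of them passed. G6pc2, an islet glucose-phosphatase subunit, was at 0.39 (SE 0.14) and Ucn3, a peptide of mature beta cells, at 0.34 (SE 0.13). Without KO replicate 3 its median was 0.14 (adjusted p = 0.0861). In KO replicate 1 alone against WT, where the spread comes from the WT libraries only, it was 0.011 (adjusted p = 0.888). The delta cell list (9 members, median -0.049, adjusted p = 0.729) held 1 gene that rose and 1 that fell adjusted over the list alone, the latter being the delta cell transcription factor gene Hhex (-0.53, SE 0.15). In KO replicate 1 alone against WT the median of the delta cell list was -0.59. It was the same with the sex covariate, which rests on that same contrast. The pancreatic polypeptide cell list had a median of 0.0060 over 6 members (adjusted p = 0.915), and the 3 tested members of the epsilon cell list, too few for camera, had one of -0.28.

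**Figure D4:**
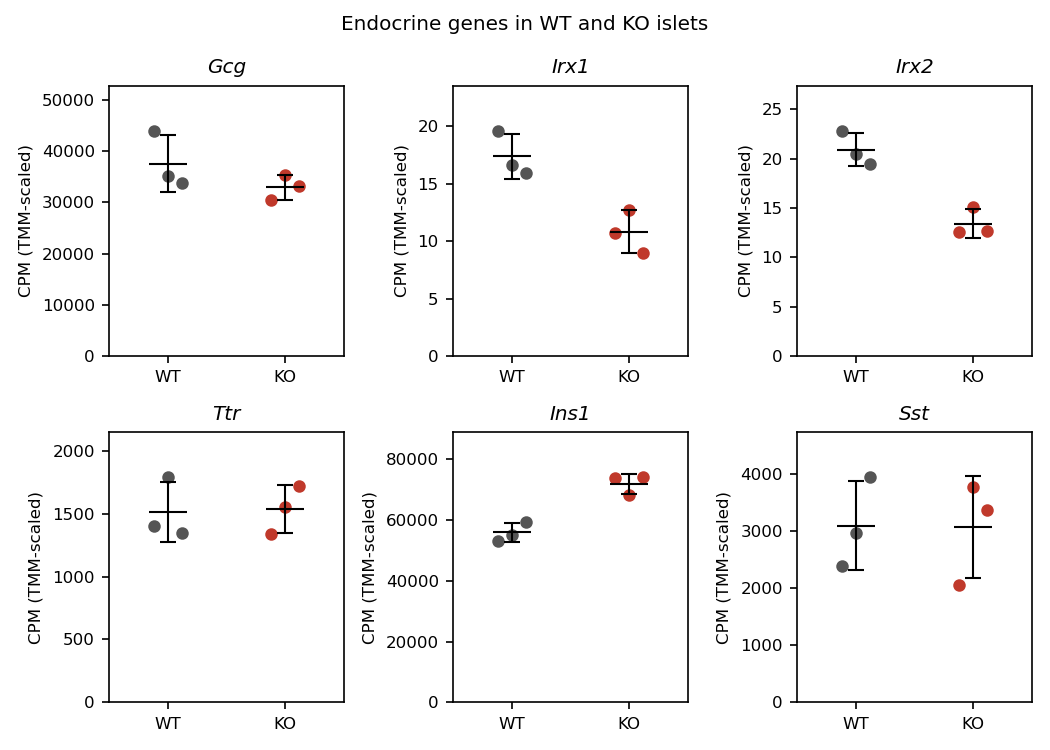
Gcg, Irx1, Irx2, Ttr, Ins1 and Sst in TMM-scaled CPM (vertical axes) in the WT and KO libraries. Points are libraries, the long bar is the mean and the whiskers are the SD. Irx2 is 20.9 ± 1.71 in WT and 13.4 ± 1.44 in KO, with no overlap.

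Broader islet regulators were lower as a list. The islet transcription factor list, which shares members with the alpha cell list, had a median of -0.14 over 26 members, 21 of them negative (camera adjusted p = 0.0041, and adjusted p = 0.646 with an estimated correlation). Adjusted over the list alone, 2 fell, 0 rose and the other 24 did not pass. The list missed the threshold without KO replicate 1 (median -0.073, adjusted p = 0.176) and without WT replicate 3 (-0.097, adjusted p = 0.0528). Neurod1, a transcription factor gene of endocrine differentiation, was at 0.06 (SE 0.16). Of 18 genes reported to be activated by PAX6, 2 fell adjusted over the list alone, among them the incretin receptor gene Gipr (-0.45, SE 0.11). The median of that list was 0.21 (camera adjusted p = 0.0923, and 0.25 with an adjusted p of 0.00489 without KO replicate 1). It shares members with the beta cell list, among them Ins1, Ins2 and G6pc2. With the sex covariate its median was -0.024, and in KO replicate 1 alone against WT it was -0.023. In the list for excitability and calcium channels (20 members, median -0.22, camera adjusted p = 0.0103, and adjusted p = 0.556 with an estimated correlation), the calcium channel genes Cacna1c (-0.65, SE 0.12) and Cacna1a (-0.70, SE 0.13) fell adjusted over the list alone. That list missed the threshold with the length and GC offsets (median -0.080, adjusted p = 0.207), without WT replicate 3 (-0.14, adjusted p = 0.101) and without KO replicate 1 (-0.13, adjusted p = 0.154). In the splicing regulator list (30 members, median -0.063, camera adjusted p = 0.0767), the neuronal-type regulators Srrm3, Elavl3 and Rbfox2 fell adjusted over the list alone, and the list passed with the offsets (-0.10, adjusted p = 0.0125), without WT replicate 2 (-0.14, adjusted p = 0.0136) and without KO replicate 3 (-0.077, adjusted p = 0.018).

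Genes of oxidative phosphorylation were higher together. All 36 tested members had positive log2 fold changes, with a median of 0.23 (camera adjusted p = 1.53e-13, and adjusted p = 0.556 with an estimated correlation). Over all genes none passed in edgeR, and adjusted over the list alone 26 rose, 0 fell and 10 did neither. Examples were Ndufb8 of complex I, from 35.3 ± 2.15 to 44.6 ± 1.36 CPM (0.34, SE 0.07), Sdhb of complex II at 0.29 (SE 0.06) and Uqcrc2 of complex III at 0.24 (SE 0.06). These are short genes, with a median exonic length of 1908 bp. Transcripts of the mitochondrial genome took 2.46 ± 0.249% of counts in WT and 2.82 ± 0.149% in KO (exact permutation p = 0.2, smallest possible 0.1).

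Among non-endocrine cells, endothelial genes were higher and acinar and Schwann cell genes lower as lists. The endothelial list had a median of 0.33 over 14 members (camera adjusted p = 7.45e-06, and adjusted p = 0.556 with an estimated correlation). Adjusted over the list alone 4 rose, 0 fell and 10 did neither: the vascular cadherin gene Cdh5 (0.45, SE 0.11), the guidance receptor gene Robo4 (0.45, SE 0.12) and the VEGF receptor genes Flt1 (0.56, SE 0.16) and Kdr (0.41, SE 0.12). The stellate cell and fibroblast list was also higher (15 members, median 0.42, camera adjusted p = 0.0169, and adjusted p = 0.651 with an estimated correlation), and none of its members passed adjusted over the list alone. It missed the threshold in limma-voom (0.31, adjusted p = 0.0611), without WT replicate 1 (0.22, adjusted p = 0.254), without KO replicate 1 (0.12, adjusted p = 0.169) and without KO replicate 2 (0.22, adjusted p = 0.113). The Schwann cell and neuron list, at low levels, had a median of -0.96 over 6 members (camera adjusted p = 0.00717, and adjusted p = 0.556 with an estimated correlation). In it 3 fell adjusted over the list alone, among them the glial transcription factor genes Sox10, from 0.682 ± 0.0834 to 0.254 ± 0.145 CPM, and Foxd3.

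Acinar cell genes, which encode digestive enzymes, took 6.04 ± 3.24% of counts in WT and 4.0 ± 1.73% in KO (exact permutation p = 0.5, smallest possible 0.1). As a list they had a median of -0.52 over 25 members, none of which passed adjusted over the list alone (camera adjusted p = 0.0081, and adjusted p = 0.668 with an estimated correlation). WT replicate 1 held the highest acinar share, 9.56%, and without it the median was 0.054 (adjusted p = 0.873). The list also missed the threshold without KO replicate 3 (-0.22, adjusted p = 0.469), with the sex covariate (-0.0066, adjusted p = 0.667) and with the acinar covariate (0.10, adjusted p = 0.101). The other lists of non-endocrine cells did not pass: duct cells (median -0.36, adjusted p = 0.0923), macrophages (0.27, adjusted p = 0.0594), lymphocytes (-0.26, adjusted p = 0.729) and erythrocytes (0.88, adjusted p = 0.074). The adipocyte and mesothelium list had 2 tested members, too few for camera, with a median of 0.79. Leaving out 1 library brought some of these lists past the threshold: lymphocytes (-0.65, adjusted p = 7.72e-06) and duct cells (-0.36, adjusted p = 0.0304) without WT replicate 3, macrophages (0.46, adjusted p = 0.000237) and erythrocytes (1.18, adjusted p = 0.0249) without KO replicate 3. Macrophages also passed without WT replicate 2 or WT replicate 3, and erythrocytes without WT replicate 2 or KO replicate 1. Macrophages (0.28, adjusted p = 0.0146) and erythrocytes (0.87, adjusted p = 0.0416) passed with no low-count filter as well. With the sex covariate, which sets KO replicate 1 alone against WT, the macrophage median was 0.49 and the erythrocyte median was -0.33.

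Lists of secretory, metabolic and stress genes had small medians. The cholesterol synthesis list, at a median of 0.15 over 20 members (camera adjusted p = 0.0119, and adjusted p = 0.651 with an estimated correlation), and the unfolded protein response list, at 0.096 over 21 (camera adjusted p = 0.0255, and adjusted p = 0.651 with an estimated correlation), were higher, with no member past adjustment over the list alone. The chaperone gene Hspa5 was at 0.13 (SE 0.10). The cholesterol list missed the threshold with the sex covariate (0.068, adjusted p = 0.667) and without WT replicate 2 (0.10, adjusted p = 0.303) or KO replicate 2 (0.10, adjusted p = 0.127). The unfolded protein response list missed it with the offsets (0.082, adjusted p = 0.0691), at 1 CPM in 3 libraries (0.076, adjusted p = 0.0602), and without WT replicate 2 (0.048, adjusted p = 0.203), WT replicate 3 (0.10, adjusted p = 0.129) or KO replicate 1 (0.070, adjusted p = 0.29). Lists that did not pass were exocytosis and granule genes (median 0.081, adjusted p = 0.0993), glycolysis and hypoxia (0.078, adjusted p = 0.074), ribosomal proteins (0.056, adjusted p = 0.0676) and immediate early and dissociation stress genes (0.22, adjusted p = 0.223). Genes of the glucagon and amino acid response (-0.070, adjusted p = 0.206), the cell cycle (0.024, adjusted p = 0.303) and the interferon response (0.071, adjusted p = 0.661) did not pass either. The cell cycle list rested on single libraries, with a median of 0.50 (adjusted p = 2.41e-07) without WT replicate 2 and 0.17 (adjusted p = 0.0243) without KO replicate 2. Leaving out 1 library also gave calls for glycolysis (WT replicate 2, adjusted p = 0.0136), the glucagon response (WT replicate 2, adjusted p = 0.0468), exocytosis (KO replicate 2, adjusted p = 0.035), immediate early genes (KO replicate 3, adjusted p = 0.000859) and ribosomal proteins (WT replicate 1, adjusted p = 0.0413, or KO replicate 3, adjusted p = 0.00597), all in the direction given above. With the sex covariate, which sets KO replicate 1 alone against WT, the medians were 0.56 for immediate early genes, 0.22 for the cell cycle and 0.11 for ribosomal proteins. With the acinar covariate immediate early genes (0.26, adjusted p = 0.0318) and ribosomal proteins (0.093, adjusted p = 0.0058) passed. Exocytosis passed with no low-count filter (0.084, adjusted p = 0.0255), in DESeq2 (0.083, adjusted p = 0.0422) and with the offsets (0.11, adjusted p = 0.0438). Glycolysis passed with no low-count filter (0.077, adjusted p = 0.0274) and with the offsets (0.13, adjusted p = 0.0147). Ribosomal proteins also passed with no low-count filter (0.068, adjusted p = 0.00488), in DESeq2 (0.059, adjusted p = 0.0171) and in limma-voom (0.055, adjusted p = 0.0277). With the length and GC offsets their median was -0.013 (adjusted p = 0.685). Genes normally kept off in beta cells had a median of -0.093 but a mean of 0.13, the direction that camera took (adjusted p = 0.559).

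**Figure D5:**
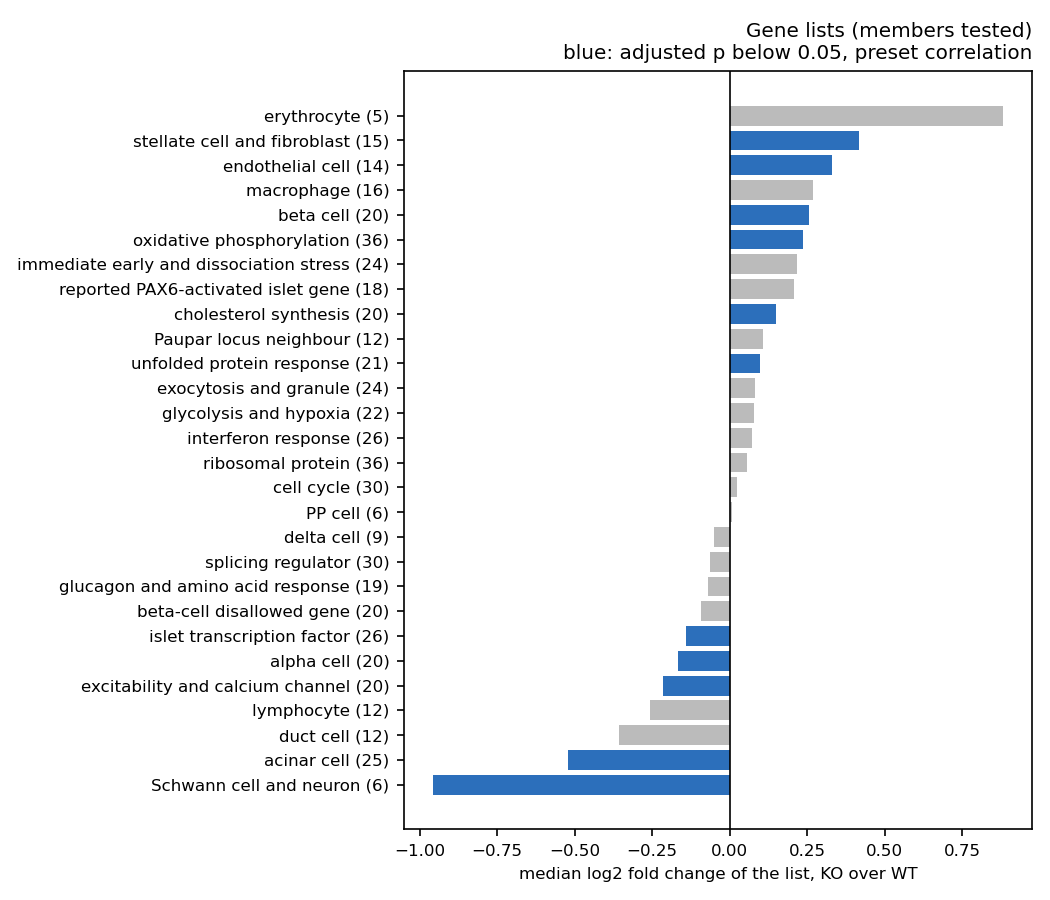
Median log2 fold change, KO over WT (horizontal axis), of the 28 gene lists tested with camera, with the number of tested members in parentheses. Blue bars are the 11 lists at an adjusted p below 0.05 with the preset correlation. None had one below 0.556 with an estimated correlation.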

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

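The sex covariate, the WT libraries against KO replicate 1 alone, and the length and GC offsets were chosen after the result was seen. With the sex covariate too, the effect of genotype rests on KO replicate 1 against the WT libraries. The 27 called genes were lower in KO under all 18 refits, with medians from -0.91 to -0.69. They were picked from these same data and their groups did not overlap, so the kept direction was largely fixed in advance. How many genes passed varied. Counts stayed within 1.5 times under DESeq2 size factors, library sizes without the 10 most abundant genes, both other filters and robust empirical Bayes. They were 437 lower and 209 higher in DESeq2, 125 lower and 7 higher at an adjusted p below 0.1, and 0 lower in limma-voom, with the acinar covariate, the sex covariate or the offsets, and in KO replicate 1 alone, where 1 gene, the immunoglobulin gene Igkv12-89, was higher. Leaving out single libraries gave 0 to 80 lower and 0 to 9 higher: 80 and 9 without WT replicate 3, 4 and 1 without KO replicate 1, and 0 without each of the others. Fits with fewer libraries or a covariate have fewer residual degrees of freedom, and otherwise the cause was not tested. In these refits the median of all genes moved by at most 0.012. Of 1580 values for 89 named genes, 1439 kept their direction and side of the threshold, 121 lost and 20 gained a call, and 0 reversed with a call.

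The replicate number as a block gave 0 lower genes, with a log2 fold change of the targeted gene, Paupar, of -5.92 (adjusted p = 0.204), and 15 gene lists, with duct cells (adjusted p = 0.0362), erythrocytes (adjusted p = 0.00205) and exocytosis (adjusted p = 0.0443) among those gained. Deviations of libraries with the same number correlated at 0.18, 0.058 and 0.032 over all tested genes, where KO replicate 3 correlated better with WT replicate 2 (0.058). Over genes above 1 log2 CPM they correlated at 0.18, 0.043 and 0.11, and each library correlated best with its own number, a hint from the data. As not every correlation passed 0.1, the libraries were taken to share only a number.

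Paupar, the targeted gene, stayed lower by a similar amount but missed the adjusted threshold in limma-voom (-6.27, adjusted p = 0.092), with the acinar covariate (-5.87, adjusted p = 0.178), the sex covariate (-5.42, adjusted p = 0.503), KO replicate 1 alone (-5.42, adjusted p = 0.566) and the offsets (-5.98, adjusted p = 0.0875). Without single libraries it ran from -6.38 to -5.42 (adjusted p 0.0348 to 0.263), and it passed without WT replicate 3 only. Depth limits it little, since the KO libraries held 8 counts against 540.

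Of the gene lists, 17 passed with no low-count filter, 8 to 15 under the other refits and 0 with an estimated correlation. The alpha cell list ran from -0.25 to -0.051 without single libraries, missing the threshold without KO replicate 1 (adjusted p = 0.0518), and it missed it at -0.17 with an estimated correlation (adjusted p = 0.556). The beta cell list missed the threshold with an estimated correlation (0.26) and without KO replicate 3, and it ran from 0.14 to 0.29 without single libraries. Its median was 0.0098 with the sex covariate and 0.011 in KO replicate 1 alone. The list of PAX6-activated genes passed, in the higher direction, with no filter (0.22), in DESeq2 (0.21), with the replicate block (0.21) and without KO replicate 1 (0.25). Without single libraries it ran from 0.12 to 0.26, but it was -0.024 with the sex covariate and -0.023 in KO replicate 1 alone. The acinar list reversed with the acinar covariate (0.10), which removes it by construction, and without WT replicate 1 (0.054). Without single libraries it ran from -0.85 to 0.054. The list of genes kept off in beta cells turned positive and passed without KO replicate 3 (0.068), and it ran from -0.22 to 0.21 without single libraries. With the sex covariate and in KO replicate 1 alone its median was 0.23. For these lists the cause was not tested.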

Other observations

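Chosen after the result was seen were the 3 gene lists of the next paragraph, the tests of sex, of alpha cell number and of transcription factors in general, the offsets themselves and the count of sample splits for genes. Chromatin regulators as a class were lower in KO islets. Of 44 such genes 43 had negative log2 fold changes (median -0.37, camera p = 8.05e-41, and p = 0.012 with an estimated correlation), and 5 of them are among the 27 called genes. With the length and GC offsets the median shrank to -0.21 (camera p = 1.59e-18 with the preset correlation). Beside these, Tet2, a DNA demethylation enzyme, was at -1.30 (adjusted p = 0.0557), and Kmt2d, a histone methyltransferase, at -1.18 (adjusted p = 0.0669). The exception was the X-linked Kdm6a, at 0.48. As 5 members were known to be called when the list was drawn up, its p is not independent evidence.

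A list of 9 noncoding RNAs known to stay in the nucleus was lower as a list, with a median of -1.60 (camera p = 3.30e-28, and p = 0.00149 with an estimated correlation), and it was -1.60 with the offsets. All 9 had negative log2 fold changes, but only Malat1, Meg3 and Neat1 passed over all genes. As these 3 were known to be called when the list was drawn up, its p is not independent evidence either. Xist, also a nuclear RNA, is not in the list and went the other way in KO replicates 2 and 3 (1120 and 862 counts, against at most 6 in each other library). Firre, an X-linked one, was at -2.32 (adjusted p = 0.0669) and Mirg, from the same imprinted cluster as Meg3, at -1.60 (adjusted p = 0.0669), while Rian, of that cluster too, was at -0.27 (adjusted p = 0.268). Basement membrane genes were higher, with a median of 0.38 over 14 members (camera p = 1.23e-07, and p = 0.0946 with an estimated correlation), beside medians of 0.33 and 0.42 in the endothelial and the stellate and fibroblast lists, which mark cells that make basement membrane. Col15a1 went from 32.0 ± 2.79 to 51.3 ± 6.00 CPM (0.68, adjusted p = 0.0867) and the laminin gene Lama4 from 12.3 ± 2.25 to 20.4 ± 0.249 CPM (0.73, adjusted p = 0.109), both without overlap between the groups.

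The called genes are long, so the trend with length and GC content could account for part of their fall. After the offsets the median of the 26 called genes with annotation was -0.679 (95% interval -0.78 to -0.52), against -0.84 (-0.99 to -0.67) before, although none then passed (smallest adjusted p = 0.0593). The test decides little, since the genes were picked for their fall in these same data. The average trend reached only -0.28, in long genes of high GC content, so removing it could hardly bring them near 0. Sex stays open: over the 27 autosomal genes with the smallest p among those lower without KO replicate 1, that library, which lacks Xist, stood at -0.77 against WT (95% interval -0.95 to -0.56), beside -0.85 for KO replicates 2 and 3, but it is a single library. These genes were also picked with the same WT libraries, so a negative value is partly built in. A smaller share of nuclear RNA cannot be told apart from an effect of genotype: 320 long noncoding genes had a median of -0.0168 after the offsets (-0.051 to 0.019), but that class holds RNAs that leave the nucleus, so the test was the wrong one and decides nothing. The 10 splits of the 6 libraries are too few for a share under 0.05: 1 of them, the real one, called as many genes (27, against 15 in the highest other).

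The lower alpha cell list may reflect fewer alpha cells, a lower level of transcription factors in general, or the trend with length. The Gcg share of counts, 3.85% in WT and 3.21% in KO, goes with the first, though Gcg did not pass in edgeR. Against the first alone, 6 transcription factors of the list had a median of -0.52 and the other 14 members one of -0.12. Relative to those others, the 6 lay lower in each KO library than in each WT library, by -0.382 on average. Against the second, they also lay lower relative to 24 other islet transcription factors without overlap, by -0.369, and the third points the other way: the list's genes have a lower median GC content (45.9%) than all tested genes (49.9%) and are shorter, so the trend would raise them, and after the offsets the median was -0.20 (camera p = 2.98e-05 with the preset correlation). In the beta cell list, which was higher, transcription factor genes also lay below the list's median of 0.26, at -0.22 to -0.014. Such a gap is thus not particular to the alpha cell list. Fewer alpha cells together with lower transcription factors in general was not tested. An effect of genotype on alpha cell regulators is a hypothesis that stays open, as does a change in alpha cells of some kind. The members were parted into transcription factors and others after their values were seen, with the zinc finger gene Peg3 among the others.

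Oxidative phosphorylation genes are short, and the trend with length could raise them, but after the offsets their median was still 0.16 (camera p = 1.13e-08 with the preset correlation), down from 0.23. Endothelial genes are longer and of higher GC content (53.2%) than all tested genes (49.9%), so the trend would lower them, and their list had a median of 0.41 after the offsets (camera p = 2.57e-11 with the preset correlation). A lower acinar share would raise every other gene by only 0.0314 on the log2 scale, below the interval of the endothelial median (0.21 to 0.43). What stays open for both lists is the genotype, the islet preparation and the other splits: 5 of the 10 splits, the real one included, called at least as many lists (11, against 18 in the highest other), and 10 are too few for a share under 0.05.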
